A study of Mus musculus with 30 samples.

How the data were processed

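RNA was measured in retinal ganglion cells, the neurons whose axons form the optic nerve, in 30 libraries from mouse retina. Per the labels' protocols, adeno-associated virus carrying sgRNAs was injected into the vitreous of LSL-Cas9-GFP; Vglut2-Cre mice, in which Cas9 is made in cells that express Vglut2. The virus carried either non-targeting sgRNAs (the NT group) or sgRNAs against Ssrp1 (the SSRP1KO group), and the optic nerve was crushed later. Cells were collected without crush (no crush) or 1, 2, 3 and 4 days post crush (dpc), which makes 10 groups of 3 libraries. The cells were dissociated with papain and sorted live by fluorescence on the CD90.2 antigen, on GFP, on the mCherry carried with the sgRNAs, or on a combination of these. Libraries were made from total RNA with a SMART-Seq low-input kit and sequenced as paired reads, per the labels' protocols. The labels do not say that the 3 libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may in part be technical.

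The authors deposited whole-number counts per gene and a second table of whole-number counts per short genomic interval annotated with a repeat family. The submitters' processing notes name the build GRCm38 (mm10), bcl2fastq 2.17, STAR and HTSeq, without saying which tool did what. The gene annotation, the strand setting and the treatment of reads that match several places are not given in the sources used here. Genes with near-identical copies, overlapping genes and antisense partners therefore carry counts that cannot be told apart. The totals of the gene table ran from 9715972 to 34420978 counts per library, with 15281 to 18504 genes detected. The gene table held 24060 symbols. Of these, 27 symbols had turned into calendar dates and were left out, at most 0.275% of the counts of a library. This left 24033 symbols. Of the 24060, 22735 (94.5%) were found in the GENCODE M21 annotation of GRCm38, which gave coordinates and lengths.

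Genes were tested with edgeR 4.0.16 in R 4.3.3. Counts were scaled with TMM, low counts were removed with filterByExpr on the 10 groups, which kept 16621 genes, and the quasi-likelihood model had 1 coefficient per group over all 30 libraries (20 residual degrees of freedom). All tests were two-sided, and p-values were adjusted with the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Each day was compared with no crush within each sgRNA group, SSRP1KO was compared with NT at each time and as the mean of the 5 differences, and the 4 differences between the crush responses were tested together with 1 F-test. CPM values are counts scaled by the TMM-scaled library size, given as mean ± SD with n = 3 per group, and log2 fold changes are given ± SE. Intervals and floors cover counting error only, since the reads carry no molecular identifiers in the deposited counts.

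The design, the gene lists and the rule for naming genes were fixed before the data were examined. The rule named Ssrp1 first. It then took the 10 genes with the largest increase and the 10 with the largest decrease for 5 comparisons (NT at 1dpc and 4dpc against no crush, and SSRP1KO against NT without crush, at 4dpc and on average). For the other comparisons it took 3 each way. A gene had to pass the threshold, reach a mean of 5 CPM in the higher group and have no overlap between the libraries of the groups, or, for the average, the same sign at all 5 times. Predicted gene models were passed over. For the difference between crush responses, the 10 genes with the smallest adjusted p were taken, and from each list the 2 members with the smallest adjusted p each way. A few of the genes so chosen are not reported here. The 32 lists covered injury, death and stress pathways, neuronal functions, chromatin, metabolism and markers of other retinal and immune cells. The list of mitochondrially encoded genes had no member in the table, and the other 31 were tested with camera in limma 3.58.1, with its preset correlation of 0.01, adjusted over the lists within a comparison. The same lists were tested with an estimated correlation and with fry.

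For the repeat table, the counts of all intervals annotated as LINE elements were expressed as a percent of the gene counts of the same library. SSRP1KO and NT were compared with a permutation test that shuffled the sgRNA labels within each time (100000 resamples). Crushed and uncrushed NT libraries were compared with an exact test over 455 splits, whose smallest possible p is 0.0022. Single LINE intervals were tested with edgeR, with the library sizes of the gene table. Intervals were placed in exons, introns or between genes with bedtools 2.31.1. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.

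No pair of replicates was duplicated: the smallest chi-square per degree of freedom between replicates of a group was 11.5. The steps were tested on simulated counts drawn from these libraries' means. For the average over times, 45 of 100 genes changed by 0.5 on the log2 scale and 64 of 100 changed by 1 were called, with 3 calls among 16221 unchanged genes. For NT 4dpc against no crush, 42 of 100 genes changed by 1 and 73 of 100 changed by 2 were called, with 2 calls among 16421 unchanged genes. For SSRP1KO against NT without crush, 3 of 100 genes changed by 0.5 and 27 of 100 changed by 1 were called. For the difference between crush responses, 14 of 100 genes changed by 1 and 67 of 100 changed by 2 were called. These genes were changed in NT 4dpc only, so the figures cover a difference on a single day. The permutation test within times passed in 3.5% of simulated data with no difference and in 98.5% with a log2 difference of 0.5, and camera called 1% of 200 lists of unchanged genes. The genes were simulated independently of each other, so this 1% does not cover lists of genes that vary together.

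Alternatives planned from the start were DESeq2 size factors, DESeq2 1.42.0 as the tool, no filter, the replicate number as a block, only the libraries of the groups compared, and each library left out in turn. For the LINE share they were other denominators, a minimum of 10 counts and the 10 highest intervals left out. A further 4 were chosen after seeing the data: a score for the sex of the animals as a covariate, scores for markers of other cells as covariates, the 3 libraries that stood apart left out, and the transcript Rn45s left out of the denominator. The 3 libraries were NT 2dpc replicate 3, SSRP1KO 2dpc replicate 5 and SSRP1KO no crush replicate 3. Each deviated from the mean of its group's other libraries by more than 1 on the log2 scale (root mean square over genes). A comparison of groups that hold none of them can change only through the fit shared by all groups. The other repeat families were looked at only after seeing the data.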

Results

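The data were counts per gene in 30 RNA libraries of sorted mouse retinal ganglion cells. They fell into 10 groups of 3 libraries: cells that received non-targeting sgRNAs (NT) and cells that received sgRNAs against Ssrp1 (SSRP1KO), each without optic nerve crush and at 1, 2, 3 and 4 days post crush (dpc). Ssrp1 encodes a subunit of FACT, a histone chaperone that opens nucleosomes for transcription. The total per library was 9715972 to 34420978 counts, with 15281 to 18504 genes detected. A second table held counts for short genomic intervals annotated with repeat families. Unless another test is named, adjusted p-values for genes come from edgeR's quasi-likelihood test and those for gene lists from camera, both two-sided.

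Ssrp1 mRNA was lower in the SSRP1KO libraries, by a mean of -0.89 ± 0.10 on the log2 scale over the 5 times (edgeR adjusted p = 2.11e-06, 15 libraries against 15). The gene lies on chromosome 2 of GRCm38, from 85037234 to 85047109 on the plus strand, with 16 exon blocks. Without crush, Ssrp1 stood at 64.7, 61.0 and 67.9 CPM in the NT libraries and at 43.4, 49.2 and 66.9 CPM in the SSRP1KO libraries, a log2 difference of -0.28 that did not pass the test (edgeR adjusted p = 0.52). At 1dpc it stood at 75.6, 80.3 and 63.0 CPM in NT and at 26.9, 29.6 and 30.1 CPM in SSRP1KO, and at 2dpc at 78.4, 90.8 and 36.1 CPM against 39.0, 39.4 and 45.4 CPM. At 3dpc the values were 80.5, 102.0 and 89.6 CPM in NT against 37.8, 38.0 and 40.5 CPM in SSRP1KO, and at 4dpc 50.6, 97.9 and 92.2 CPM against 48.0, 44.1 and 41.7 CPM. Ssrp1 fell by 1.34 ± 0.23 at 1dpc (edgeR adjusted p = 0.0203), by 1.23 ± 0.23 at 3dpc (0.00896) and by 0.85 ± 0.23 at 4dpc (0.023), while the difference of -0.74 at 2dpc did not pass (0.11). The library labelled SSRP1KO no crush replicate 3 (66.9 CPM) lay in the range of the NT libraries, and the library labelled NT 2dpc replicate 3 (36.1 CPM) lay below all SSRP1KO libraries of its day. Indels made by Cas9 need not remove an mRNA, so the level checks the labels only as far as the mRNA falls. The call at 1dpc did not pass with the replicate block (0.060), without NT replicate 1 (0.20) or 2 (0.21) or any SSRP1KO 1dpc replicate (0.26, 0.19 and 0.18), and that at 3dpc did not pass without NT replicate 2 (0.063).

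**Figure D1:**
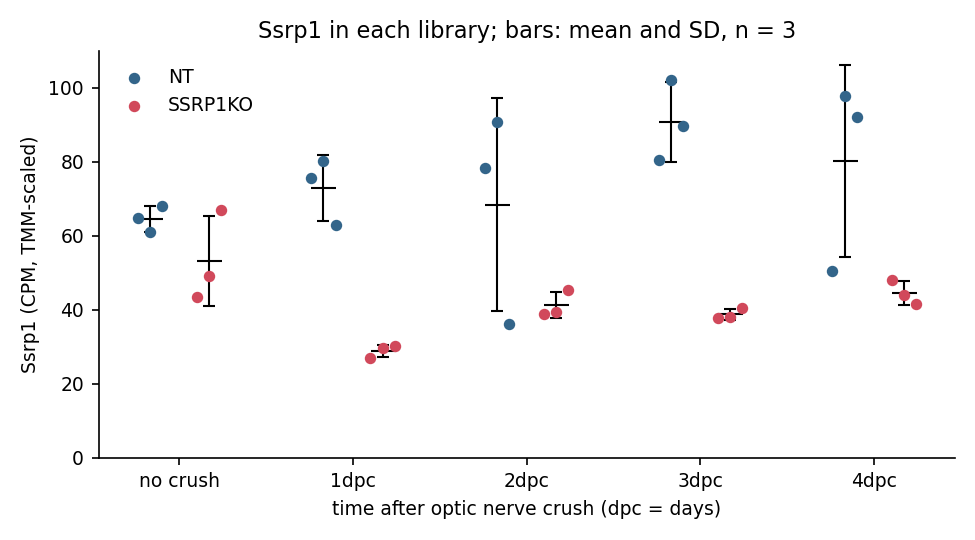
Ssrp1 level in each library, in CPM on the TMM-scaled library size (y axis, from 0), against the time after optic nerve crush (x axis); points are libraries and bars the mean and SD of 3. The points of SSRP1KO 1dpc lie between 26.9 and 30.1 CPM and those of NT 1dpc between 63.0 and 80.3 CPM, while the library labelled NT 2dpc replicate 3 lies at 36.1 CPM and the library labelled SSRP1KO no crush replicate 3 at 66.9 CPM.

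The NT libraries gave the time course of the crush response in control cells. At 1dpc the largest increases were in Creb5, a CREB-family transcription factor (0.409 ± 0.545 CPM without crush and 32.2 ± 4.52 CPM at 1dpc, n = 3 each), and in the metalloproteinase gene Mmp12 (2.38 ± 2.83 and 89.5 ± 7.53 CPM). Hrk, a pro-apoptotic BH3-only gene, rose by 4.29 ± 0.44 (edgeR adjusted p = 2.69e-07), and Dusp16, a phosphatase that acts on JNK, rose by 4.12 ± 0.19 (7.95e-15). Atf3, a transcription factor induced by axon injury, rose by 3.81 ± 0.29 (7.81e-10). The mechanotransduction channel gene Tmc1 rose by 4.32, the stress pseudokinase gene Trib3 by 4.02, the immune receptor gene Gp49a by 3.99, Arid5a by 3.91 and the TWEAK receptor gene Tnfrsf12a by 3.46. Decreases were smaller: the tubulin gene Tubb4b fell by 1.15 ± 0.20 (0.000566) to 96.1 CPM, the tubulin-binding gene Tppp3 by 0.98 to 217 CPM, and the histamine receptor gene Hrh3 by 1.37. Ccne1, Exosc6, Pcdh18, Rhobtb2, Wnt2b, Prlr and Pdgfa fell by 0.95 to 1.13. In all, 309 of 16621 genes changed, 230 up and 79 down. Of the 20 named genes, 9 passed in every alternative, all of them among the increases. Xist stood at 1053 to 1686 CPM in the NT 1dpc libraries and at 190, 0.364 and 0.697 CPM in the uncrushed ones, so the mix of sexes differed between the groups. Genes of the Y chromosome together stood at 0.0473, 27.5 and 48.0 CPM at 1dpc and at 184, 167 and 188 CPM without crush. Some libraries thus held RNA of both sexes, as cells pooled from male and female animals would. With a score for the sex of the animals as a covariate the count was 159 (137 up, 22 down), DESeq2 gave 575, the fit of these 6 libraries alone gave 880 (404 up, 476 down), and 998 (605 up, 393 down) changed without the 3 libraries that stood apart from their groups. None of those 3 was in the groups compared here. Without single libraries the count was 167 (NT 1dpc replicate 1), 181 (NT 1dpc replicate 3), 191 (NT no crush replicate 1) or 162 (NT no crush replicate 2).

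At 4dpc the control cells had a much larger response, with 4513 genes changed, 2322 up and 2191 down. Colec10, a secreted collectin, had no count in the uncrushed NT libraries and reached 43.7 ± 10.7 CPM (n = 3), at least 1049-fold against a floor of 3 counts over the group, and the receptor gene Trhr2 went from no count to 6.58 ± 1.02 CPM, at least 158-fold against the same floor. Ecel1, a neuronal peptidase induced by nerve injury, rose by 8.19 ± 0.58 (edgeR adjusted p = 1.04e-11) from 2.01 ± 0.472 to 581 ± 123 CPM. Mmp12 rose by 8.13 ± 0.52 (1.25e-12) to 690 ± 133 CPM, and Sprr1a, a gene of regenerating axons on chromosome 3 from 92483952 to 92485895, rose by 8.01 ± 0.97 (1.83e-07) to 377 ± 14.5 CPM. The neuropeptide gene Nts (13.6 CPM) and the casein gene Csn3 (11.2 CPM) rose from a single count in the uncrushed libraries, and Mustn1, Cdsn and Dusp9 also rose from 1 or 2 counts. The nicotinic receptor gene Chrna6 fell by 5.28 ± 0.29 (6.8e-14), from 528 ± 31.8 to 13.3 ± 4.23 CPM, and the peptidase gene Mme fell by 5.23 ± 0.54 to 0.695 CPM. The sodium channel subunit gene Scn4b fell by 5.66, the cytokine subunit gene Il12a by 5.99, the thyrotropin-releasing hormone receptor gene Trhr by 5.37 and Sptssb by 5.02. Dnah6, Kif6 and Cox4i2 fell by 4.65 to 4.94. All 20 genes of the naming rule passed in every alternative. Xist stood at 190, 0.364 and 0.697 CPM in the uncrushed NT libraries and at 3023 to 4353 CPM at 4dpc, so the mix of sexes differed between these groups. Genes of the Y chromosome together stood at 74.9, 0 and 76.6 CPM at 4dpc. The count was 2909 with the sex score as a covariate.

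On the days between, 3128 genes changed at 2dpc (1574 up, 1554 down) and 4015 at 3dpc (1979 up, 2036 down). At 2dpc Colec10 reached 6.38 CPM from no count, at least 153-fold against the floor of 3 counts over the group, and Sprr2g, a relative of Sprr1a, reached 10.6 CPM from a single count. Mmp12 rose by 7.38, while Scn4b fell by 4.68, the Ras activator gene Rasgrp2 by 3.46 and the cholecystokinin gene Cck by 3.35. At 3dpc Colec10 reached 39.5 CPM from no count (at least 949-fold), the homeobox gene Hoxb9 went from no count to 6.21 CPM, at least 149-fold against the floor of 3 counts over the group, and Nts reached 17.5 CPM. The interferon-induced genes Ifi44, Iigp1 and Gbp3 fell by 6.55, 5.94 and 5.83 at 3dpc, but these decreases rested on NT no crush replicate 3, without which the edgeR adjusted p was 0.12, 0.30 and 0.20. The fit of the 6 libraries alone called 1870 genes at 2dpc.

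**Figure D2:**
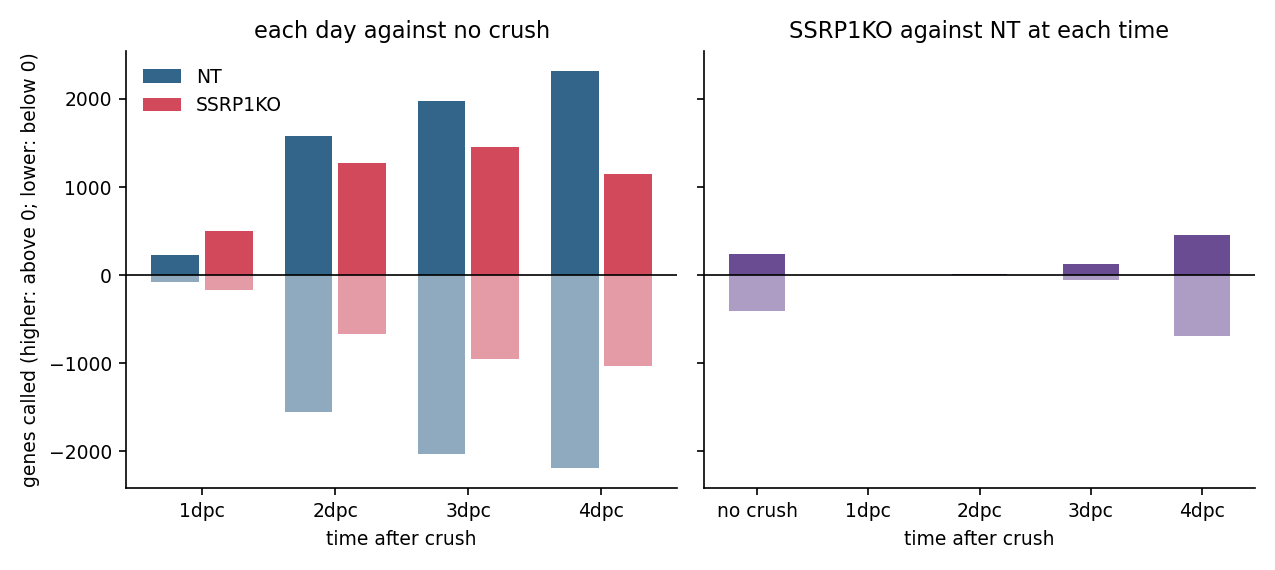
Number of genes past an adjusted p of 0.05 in edgeR (y axis, increases above 0 and decreases below it) by time after crush (x axis); the left panel compares each day with no crush within NT and within SSRP1KO, and the right panel compares SSRP1KO with NT at each time. NT counts run from 309 at 1dpc to 4513 at 4dpc, SSRP1KO counts reach 2414 at 3dpc, and SSRP1KO against NT runs from 3 at 1dpc to 1149 at 4dpc.

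Injury and stress programs rose in the NT cells from the first day. Of 34 measured genes of the integrated stress response, 17 rose at 1dpc (27 adjusted over the list alone) and 32 at 4dpc, with none down. Their median was 1.23 at 1dpc (camera adjusted p = 6.01e-50, and adjusted p = 0.00141 with an estimated correlation) and 2.58 at 4dpc (5.39e-38, and adjusted p = 0.00296 with an estimated correlation). Its members Ddit3, the CHOP transcription factor, rose by 2.51 ± 0.27 at 1dpc, and Shmt2, a mitochondrial serine enzyme, by 3.03 ± 0.23 at 4dpc. Of 25 regeneration-associated genes, 10 rose at 1dpc (4.95e-23, and adjusted p = 0.000989 with an estimated correlation) and 20 at 4dpc with a median of 2.30 (1.02e-26, and adjusted p = 0.00042 with an estimated correlation), and none fell. The transcription factor gene Sox11 rose by 2.88 ± 0.20 at 1dpc and by 4.89 ± 0.22 at 4dpc. Of 27 p53 targets, 4 rose at 1dpc (0.00218, and adjusted p = 0.00925 with an estimated correlation), and 12 rose and 2 fell at 4dpc (median 0.79, 0.000109, and adjusted p = 0.00212 with an estimated correlation), among them Cdkn1a, the p21 cell cycle inhibitor (5.36 ± 0.29), and Gadd45a (4.58 ± 0.37). Of 22 genes of the apoptosis machinery, 3 rose at 1dpc (1.92e-05, and adjusted p = 0.00141 with an estimated correlation), and 7 rose and 1 fell at 4dpc (median 0.35, 0.00213, and adjusted p = 0.014 with an estimated correlation). The BH3-only genes Bcl2l11 and Hrk rose by 4.46 ± 0.29 and 6.49 ± 0.48 at 4dpc, while the survival gene Bcl2l2 fell by 0.78 ± 0.20.

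Genes of neuronal function and lipid synthesis fell in the NT cells. Of 21 genes of cholesterol biosynthesis, none passed at 1dpc by edgeR in the fit of all libraries, and 18, 18 and 19 fell at 2dpc, 3dpc and 4dpc, with a median of -1.51 at 4dpc (camera adjusted p = 1.93e-19, and adjusted p = 0.00296 with an estimated correlation). The sterol regulator gene Srebf2 fell by 1.23 ± 0.13. Of 21 voltage-gated channel genes, 16 fell and 1 rose at 4dpc (median -1.32, 1.93e-19, and adjusted p = 0.00296 with an estimated correlation). The sodium channel gene Scn8a fell by 1.83 ± 0.12 and the potassium channel gene Kcna2 by 2.25 ± 0.16. Of 20 synaptic vesicle genes, 13 fell and 1 rose (median -0.85, 4.31e-11, and adjusted p = 0.0152 with an estimated correlation), with Cplx2 down by 1.77 ± 0.14 and the glutamate transporter gene Slc17a6, which is Vglut2, up by 0.62 ± 0.21. Of 20 genes of ganglion cell identity, 13 fell and 3 rose (median -0.78, 1.01e-10, and adjusted p = 0.0157 with an estimated correlation). Chrnb3 fell by 3.15 ± 0.17, and the growth-associated genes Gap43 and Stmn2 rose by 2.38 ± 0.25 and 0.63 ± 0.17. Of 20 subtype markers, 10 fell and 3 rose (median -0.75, 0.000128), a call not kept with an estimated correlation (adjusted p = 0.0776 with an estimated correlation).

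Of 20 genes of endoplasmic reticulum protein folding, 9 rose and 1 fell in the NT cells at 4dpc (median 0.23, camera adjusted p = 0.00415, and adjusted p = 0.0424 with an estimated correlation), with the chaperone gene Hspa5 up by 1.59 ± 0.19. Of 20 genes of FACT and other histone chaperones, 9 rose and 2 fell (0.0138), and of 19 JAK-STAT genes 9 rose and none fell (0.00145), but both calls were lost in the stricter test (adjusted p = 0.053 and adjusted p = 0.0776 with an estimated correlation). Of 18 NRF2 and oxidative stress genes, 8 rose and 2 fell (0.00303, and adjusted p = 0.0946 with an estimated correlation), with Hmox1, heme oxygenase, up by 3.57 ± 0.25 and Nqo1 down by 2.75 ± 0.56. Of 77 cytosolic ribosomal protein genes, 38 rose (median 0.59, 7.48e-06, and adjusted p = 0.287 with an estimated correlation). Of 80 nuclear genes of oxidative phosphorylation, 24 fell and 3 rose (median -0.24, 0.00171, and adjusted p = 0.61 with an estimated correlation). The list of DLK-JNK and AP-1 genes as a whole did not pass (4 up, 5 down of 18, camera adjusted p = 0.631), although Jun, the AP-1 transcription factor, rose by 2.35 ± 0.20. The 25 DNA repair genes (3 up, 0.831), 21 genes of transposon silencing and nucleic acid sensing (2 up, 1 down, 0.265) and 19 histone genes (2 up, 3 down, 0.782) did not pass either.

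**Figure D3:**
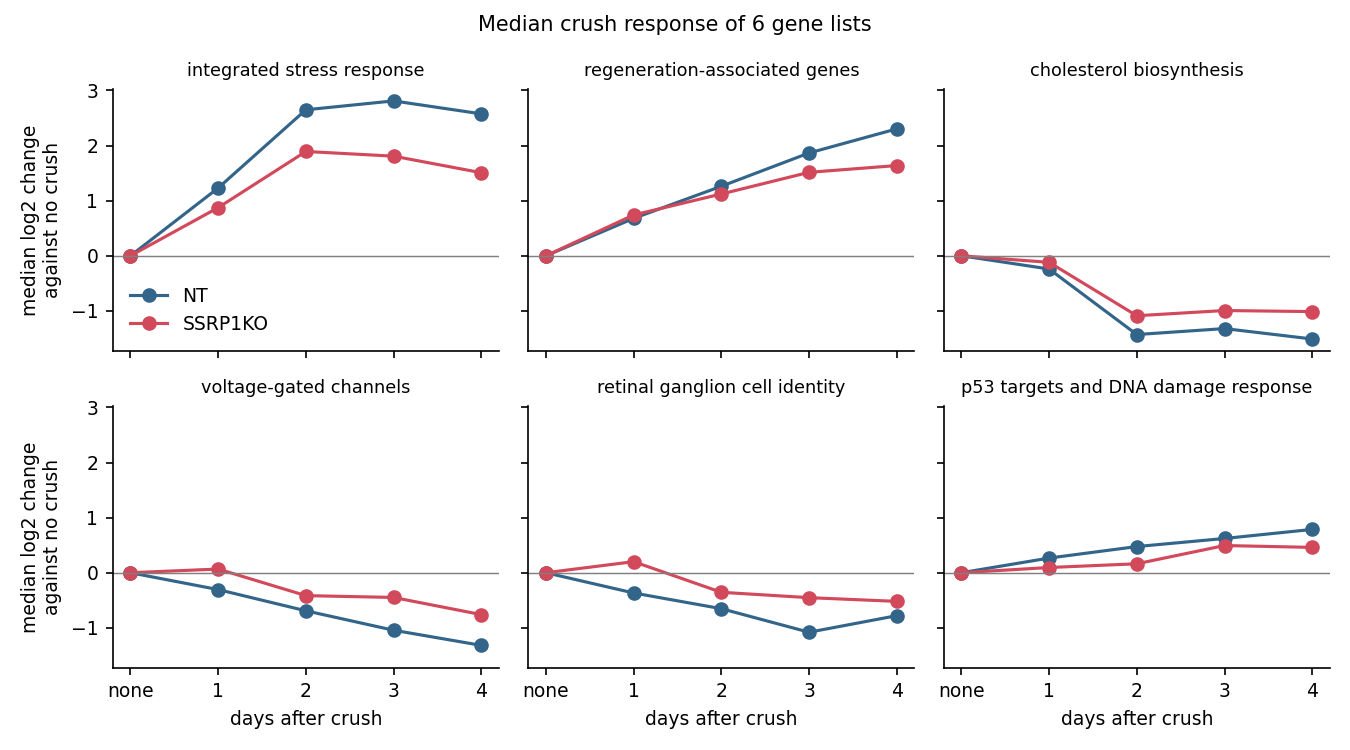
Median log2 change against no crush of 6 gene lists (y axis of each panel) by days after crush (x axis), for NT and SSRP1KO; lines join the medians of the list's measured genes. The integrated stress response reaches 2.58 in NT and 1.51 in SSRP1KO at 4dpc, and cholesterol biosynthesis reaches -1.51 and -1.01.

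The crush response of the SSRP1KO cells covered 672 genes at 1dpc (504 up, 168 down), 1939 at 2dpc (1270 up, 669 down), 2414 at 3dpc (1458 up, 956 down) and 2174 at 4dpc (1144 up, 1030 down). At 4dpc Colec10 rose to 35.9 ± 1.38 CPM and Bpifc to 12.3 CPM, each from a single count, and the axon guidance gene Sema3c rose by 8.39 ± 0.50 (edgeR adjusted p = 2.34e-12) to 37.2 ± 0.378 CPM. The growth factor gene Fgf18 fell by 3.27 ± 0.71 (0.00167), and the macrophage genes Atp6v0d2 and Mrc1 fell by 4.15 and 3.71. These last 2 calls did not pass without the library labelled SSRP1KO no crush replicate 3 (adjusted p = 0.34 and 0.23), nor without any SSRP1KO 4dpc library (0.086 to 0.13). At 3dpc the largest increase of the naming rule was in the Y-linked gene Ddx3y (10.57 ± 2.38, edgeR adjusted p = 0.00228). Y-linked genes together stood at 116, 0.603 and 119 CPM at 3dpc and at 0.0852, 0 and 0.120 CPM without crush, so sex differed between these groups. Colec10 reached 29.0 CPM from a single count at 3dpc and Sprr2g 6.15 CPM from none, at least 116-fold against the floor of 3 counts over the group. Fgf18, Scn4b and Sptssb fell by 3.21, 3.15 and 2.96. The integrated stress response rose in 27 of 34 genes at 4dpc (median 1.51, camera adjusted p = 3.18e-36, and adjusted p = 0.00667 with an estimated correlation), with Ddit3 up by 3.33 ± 0.28. Of the regeneration-associated genes 17 of 25 rose (median 1.64, 2.78e-28, and adjusted p = 0.000497 with an estimated correlation). Of the cholesterol genes 15 of 21 fell (median -1.01, 2.09e-15, and adjusted p = 0.00948 with an estimated correlation), and of the channel genes 13 of 21 (median -0.76, and adjusted p = 0.00978 with an estimated correlation). Of the identity genes 9 fell and 1 rose (median -0.52, 7.22e-09, and adjusted p = 0.029 with an estimated correlation). Apoptosis genes rose in 4 and fell in 1 of 22 (median 0.24, 0.0017, and adjusted p = 0.0135 with an estimated correlation), with the BH3-only gene Bcl2l11 up by 3.24 ± 0.28.

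The largest changes in SSRP1KO at 1dpc and 2dpc were in genes of the sex chromosomes. Ddx3y, Kdm5d and Uty, which lie on the Y chromosome, rose by 11.74, 10.95 and 10.56 at 1dpc and by 11.88, 11.49 and 10.66 at 2dpc, and Xist, the RNA of the inactive X chromosome, fell by 12.67 and 12.01. In the uncrushed SSRP1KO libraries Xist stood at 1946, 1293 and 2608 CPM, and in those of 1dpc it stood at 0.213, 0.507 and 0.188 CPM, so sex differed between these groups. H2-M2 and Phxr4 fell by 6.43 and 2.65 at 1dpc, and Mrc1 and Tigd5 by 5.36 and 3.19 at 2dpc. With the sex score as a covariate 154 genes passed at 1dpc and 885 at 2dpc, and none of the 12 named changes at these 2 times did. For Ddx3y the change was then 4.16 at 1dpc and 4.27 at 2dpc, and for Xist -1.36 and -0.65. For H2-M2 (-5.97), Mrc1 (-4.61) and Tigd5 (-3.42) it stayed about as large with a larger error (3.06, 2.28 and 1.34). The fall of Tigd5 rested on the library labelled SSRP1KO no crush replicate 3, without which it was -0.97 (adjusted p = 0.45), and those of H2-M2 and Mrc1 were then -5.43 (0.081) and -4.25 (0.046). At 1dpc DESeq2 gave 1084 genes (655 up, 429 down), the 6 libraries alone gave 268, and 1772 passed without the 3 libraries that stood apart. Without single libraries of 1dpc the count was 330 (replicate 1), 277 (replicate 2) or 407 (replicate 3). At 2dpc the 6 libraries alone gave 192 genes, and at 3dpc they gave 1157.

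SSRP1KO against NT without crush asked what the sgRNAs changed in uninjured cells. Atf3 was higher in SSRP1KO by 2.05 ± 0.29 (edgeR adjusted p = 0.00041), at 13.5 ± 5.89 against 3.25 ± 1.03 CPM (n = 3 each), and Cdkn1a by 1.44 ± 0.25 (0.0032). The increases of the naming rule included genes of macrophages and other myeloid cells (Mrc1 4.87, Wfdc17 4.69, Gp49a 4.55, and Clec7a 4.55 ± 0.91 at 23.9 ± 22.7 CPM). The lens crystallin gene Cryba1 (7.11), the adhesion gene Vcam1 (5.58), Myof (4.52), the transporter gene Slc6a12 (4.13 ± 0.58), the tachykinin gene Tac2 (4.05, at 49.6 ± 61.3 CPM) and H2-M2 (from a single count in NT) were also higher. The decreases were led by the Y-linked genes Ddx3y (-11.47), Kdm5d (-10.97), Uty (-10.60) and Eif2s3y, followed by Ifit1 (-4.19 ± 1.11), Prokr1 (-1.91), Zfp105 (-1.75), Pars2 (-1.53), Lrriq1 (-1.52) and Chrm2 (-1.45). The Ifit1 difference rested on NT no crush replicate 3 (263 CPM, against 9.25 and 7.57 CPM in the other 2), without which it was -0.71 (adjusted p = 0.74). None of the 20 named genes passed in every alternative, and 12 did not pass without some single library. In all 650 genes passed, 239 higher and 411 lower. All SSRP1KO libraries of this comparison had high Xist (above), and Xist stood at 190, 0.364 and 0.697 CPM in the NT ones, so sex and sgRNA overlapped. With the sex score as a covariate 19 genes passed, and 19 of the 20 named genes did not. The difference was then -5.69 for Ddx3y, but 4.34 for Mrc1, 5.51 for Clec7a and 9.45 for Cryba1, which stayed about as large or became larger. The comparison included the library labelled SSRP1KO no crush replicate 3, without which 1192 genes passed, and 2416 passed without all 3 libraries that stood apart. Without NT no crush replicates 1, 2 and 3 the counts were 372, 182 and 160, and without SSRP1KO no crush replicates 1 and 2 they were 386 and 291. DESeq2 gave 1222 genes (650 higher, 572 lower), the 6 libraries alone gave 14 (7 each way), the other-cell scores as covariates gave 993 and the replicate block gave 978.

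Among the lists, genes of ganglion cell identity and excitability were lower in uncrushed SSRP1KO cells. Of 20 identity genes 9 were lower (13 adjusted over the list alone; median -0.56, camera adjusted p = 2.39e-14, and adjusted p = 0.0254 with an estimated correlation), with the nicotinic receptor gene Chrnb3 at -1.0 ± 0.16 and the transcription factor gene Ebf1 at -0.79 ± 0.13. Of 21 voltage-gated channel genes 11 were lower (median -0.49, 7.77e-13, and adjusted p = 0.04 with an estimated correlation), with Kcnd2 at -1.30 ± 0.24. Of the synaptic vesicle genes 1 was lower (median -0.39, 8.5e-07, and adjusted p = 0.19 with an estimated correlation). Of 19 microglia and macrophage markers 6 were higher (12 adjusted over the list alone; median 1.58, 2.96e-08, and adjusted p = 0.246 with an estimated correlation), with Tyrobp at 3.22 ± 0.67. Amacrine markers were higher in 3 of 13 genes (median 1.21, 8.05e-05, and adjusted p = 0.219 with an estimated correlation), among them Th, tyrosine hydroxylase, at 4.60 ± 1.11. Macroglia markers were higher in 2 of 16 (median 0.72, 0.0126, and adjusted p = 0.292 with an estimated correlation), and T cell and neutrophil markers in 1 of 9 (median 2.07, and adjusted p = 0.206 with an estimated correlation). The macroglia marker Apoe stood at 694 CPM in the library labelled SSRP1KO no crush replicate 3, against 97.6 and 132 CPM in replicates 1 and 2. Sex and sgRNA overlapped in this comparison (19 genes passed with the sex score, against 650), and the shares of intronic repeats were higher in SSRP1KO as well, by 1.66 for B2, 1.06 for Alu and 0.88 for B4 on the log2 scale.

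On the first 3 days after crush few genes differed between SSRP1KO and NT. At 1dpc 3 genes passed: the heat shock gene Hspa1a was higher by 1.45 ± 0.25 (edgeR adjusted p = 0.0203; 48.5 ± 3.85 against 17.8 ± 2.65 CPM), and Ssrp1 and the chromatin remodeller gene Chd2 (-0.92 ± 0.15, 0.0203) were lower. Xist stood at 0.188 to 0.507 CPM in the SSRP1KO libraries of this day and at 1053 to 1686 CPM in the NT ones, so sex and sgRNA overlapped. With the sex score as a covariate Hspa1a (1.00, adjusted p = 0.46) and Chd2 (-0.80, 0.22) did not pass. Hspa1a did not pass without any of the 6 libraries either (0.064 to 0.44). At 4dpc Xist was high in both groups (2260 to 3236 CPM in SSRP1KO and 3023 to 4353 CPM in NT). Chd2 then stood at 85.5, 97.4 and 82.9 CPM in SSRP1KO and 217, 193 and 180 CPM in NT. Hspa1a stood at 37.6, 34.3 and 36.5 against 15.4, 19.0 and 24.1 CPM. These values argue against sex as the whole cause at 4dpc, though some NT libraries also held Y-linked RNA. At 1dpc itself sex and sgRNA cannot be told apart. Of 18 dissociation and immediate early genes 1 was higher, 8 adjusted over the list alone (median 0.84, camera adjusted p = 5.91e-26, and adjusted p = 0.00222 with an estimated correlation). Of 30 interferon-stimulated genes none passed over all genes and 26 were lower adjusted over the list alone (median -3.08, 1.26e-47, and adjusted p = 0.0119 with an estimated correlation). Ifit1, a marker of the interferon response, stood at 210, 333 and 133 CPM in NT 1dpc and at 11.7, 13.3 and 13.0 CPM in SSRP1KO 1dpc. In the uncrushed NT libraries Ifit1 stood at 9.25, 7.57 and 263 CPM, and at 3dpc at 4.13, 2.83 and 3.54 CPM, so it varied within the NT group as well. DESeq2 gave 29 genes at 1dpc, no filter gave 8, the other-cell scores gave 10, the 6 libraries alone 345, and 50 passed without the 3 libraries apart. Without any of the 6 libraries the count was 0 to 2 with edgeR. In the full fit 839 of 16621 genes had an unadjusted p under 0.05, about the share expected with no difference.

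At 2dpc 14 genes passed, 12 higher and 2 lower. Ccdc33 (4.09), the IGF binding protein gene Igfbp5 (1.52) and Sh3bgr (1.44) were higher, and Glcci1 (-1.11) and the deubiquitinase gene Usp11 (-0.90) were lower. The count was 0 with the 6 libraries alone, with the other-cell scores and with the sex score in edgeR, where 2961 genes had an unadjusted p under 0.05 in the full fit. It was 639 with DESeq2 (429 higher, 210 lower), 26 with no filter and 5 without the 3 libraries apart. Without NT 2dpc replicate 1, replicate 2 or the library labelled NT 2dpc replicate 3 it was 61, 0 and 0, and without SSRP1KO 2dpc replicates 3, 4 and 5 it was 736, 125 and 1. At 3dpc 184 genes passed, 125 higher and 59 lower. Il12a was higher by 4.10 ± 0.66 (edgeR adjusted p = 0.00222; 6.93 against 0.401 CPM) and Mme by 3.08 ± 0.48 (0.00152; 12.3 against 1.45 CPM), along with the MHC class II gene H2-Aa (3.58). Lix1 (-1.43), the GABA receptor subunit gene Gabrg3 (-1.33) and Ssrp1 were lower. Il12a and Mme passed in every alternative, and the other 4 named genes did not. Cone and rod markers were higher in 8 of 9 and 11 of 16 genes adjusted over the list alone, with none over all genes (camera adjusted p = 0.000709 and 0.000319, and adjusted p = 0.469 and adjusted p = 0.471 with an estimated correlation). Counts at 3dpc were 568 with DESeq2, 705 with the 6 libraries alone (298 higher, 407 lower), 290 with the block and 1071 without the 3 libraries apart. They were 19, 20 and 22 without NT 3dpc replicates 1, 2 and 3, and 82, 55 and 116 without SSRP1KO 3dpc replicates 1, 2 and 3.

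At 4dpc 1149 genes differed between SSRP1KO and NT, 456 higher and 693 lower. Lower in SSRP1KO were Gap43, the growth-associated protein, by -1.63 ± 0.24 (edgeR adjusted p = 0.00016; 314 ± 14.6 against 975 ± 568 CPM, n = 3 each) and the stress gene Gadd45a by -1.59 ± 0.33 (0.00338). Without NT 4dpc replicate 1 the difference was -1.03 for Gap43 (adjusted p = 0.0015) and -0.88 for Gadd45a (0.084). Atf3 stood at 274, 239 and 264 CPM in SSRP1KO against 586, 505 and 532 CPM in NT, a log2 difference of -1.06 ± 0.25 (0.0091), and Sprr1a stood at 147, 119 and 145 against 369, 394 and 369 CPM. Higher in SSRP1KO were Il12a by 5.93 ± 0.82 (7.76e-05), Mme by 3.81 ± 0.52 (7.76e-05; 11.3 ± 2.56 against 0.695 ± 0.752 CPM) and Chrna6 by 2.01 ± 0.26 (5.4e-05). The sodium channel gene Scn11a (5.34), the serotonin synthesis gene Tph2 (5.03), Rab26 (3.33), the relaxin receptor gene Rxfp3 (2.79), the nicotinic receptor gene Chrnb4 (2.65 ± 0.39) and Tmc1 (2.58) were higher as well, as were Mc1r (2.89) and Enkur (2.75). The reticulon gene Rtn4 (-1.48 ± 0.25, 1902 ± 74.9 against 5322 ± 2892 CPM), Scg2 (-1.62), Ano4 (-1.49 ± 0.21) and Gabrg3 (-1.50) were lower, and so were Ifi44 (-4.07), Inhbb (-2.42), Cth (-1.77) and Gt(ROSA)26Sor (-1.65). Without NT 4dpc replicate 1 the difference was -0.92 for Rtn4 (adjusted p = 0.013), -1.0 for Scg2 (0.011), -0.76 for Gt(ROSA)26Sor (0.39), -1.57 for Inhbb (0.20) and -3.26 for Ifi44 (0.19), and Cth (0.14), Mc1r (0.13) and Enkur (0.11) did not pass either. Of the 20 named genes 13 passed in every alternative, and 7 did not pass in at least 1 fit with a library left out. The number of genes was 553 without NT 4dpc replicate 1, 464, 536 and 518 without SSRP1KO 4dpc replicates 1, 2 and 3, and 2460 without the 3 libraries that stood apart. None of those 3 was a 4dpc library.

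**Figure D4:**
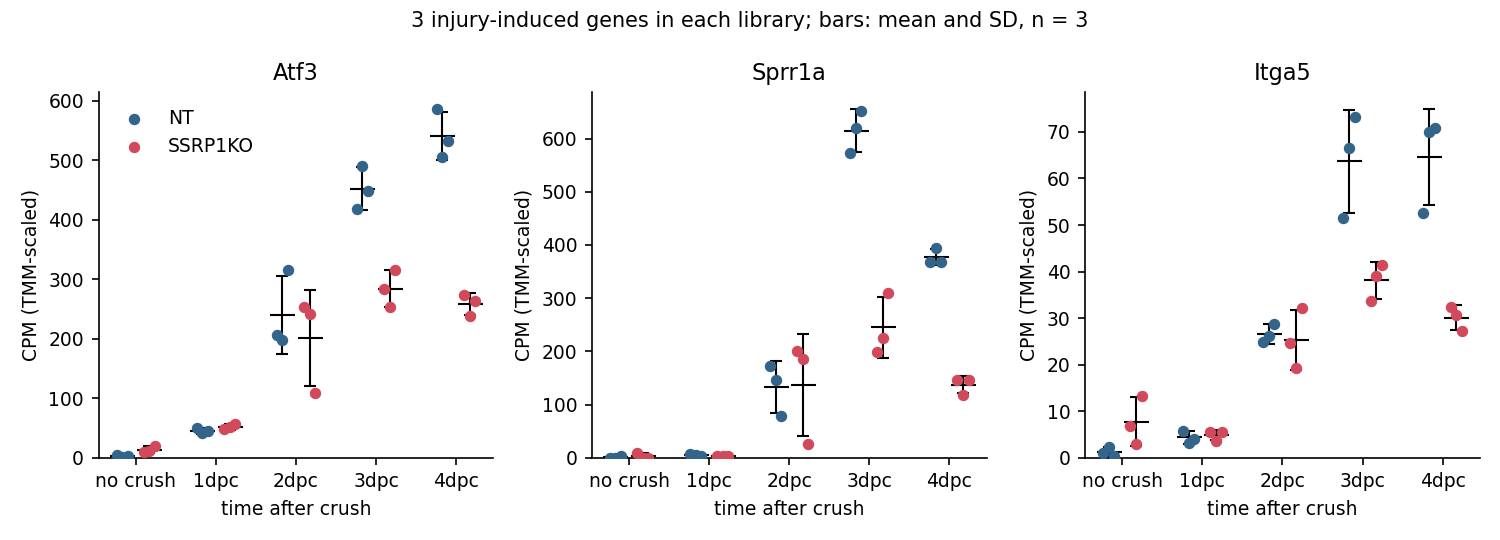
Levels of 3 injury-induced genes in each library, in CPM on the TMM-scaled library size (y axes, from 0), against the time after crush (x axes); points are libraries and bars the mean and SD of 3. At 4dpc the Atf3 points lie between 505 and 586 CPM in NT and between 239 and 274 CPM in SSRP1KO.

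Of the injury lists at 4dpc, 2 were lower in SSRP1KO with the preset correlation, and neither with an estimated correlation. Of 25 regeneration-associated genes 10 were lower and none higher (13 lower adjusted over the list alone; median -0.60, camera adjusted p = 4.33e-10), with the adhesion gene Chl1 at -1.12 ± 0.17, but the call was lost in the stricter test (adjusted p = 0.0732 with an estimated correlation). Of 34 integrated stress response genes 9 were lower and none higher (14 adjusted over the list alone; median -0.61, 4.33e-10, and adjusted p = 0.358 with an estimated correlation), with the asparaginyl-tRNA synthetase gene Nars at -0.90 ± 0.21. Of the p53 targets 3 were lower and 2 higher (median -0.19, 0.377): Gadd45a and Cdkn1a (-0.96 ± 0.24) were among the former and the kinase gene Plk2 (1.15 ± 0.16) among the latter. Identity genes went both ways, 3 higher and 6 lower (median -0.34, 0.0519), with Chrna6 higher and Ebf1 (-0.88 ± 0.13) lower. Of the chaperones of the endoplasmic reticulum 2 were lower (0.032, and adjusted p = 0.227 with an estimated correlation), with the stress sensor gene Atf6 at -0.77 ± 0.11, and Ssrp1 was the member of the FACT list that passed (0.038, and adjusted p = 0.227 with an estimated correlation). No apoptosis gene passed by edgeR (22 measured, median -0.05, 0.576). Of 18 dissociation and immediate early genes 5 were higher (median 0.63, 0.000497, and adjusted p = 0.43 with an estimated correlation), with Npas4, an activity-dependent transcription factor, at 2.33 ± 0.53.

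Averaged over the 5 times, 3296 genes differed between SSRP1KO and NT, 1602 higher and 1694 lower. Il12a was higher by 2.85 ± 0.29 (edgeR adjusted p = 3.93e-07, 15 libraries against 15), Scn11a by 3.22 ± 0.40 (4.45e-06; 5.93 against 0.812 CPM), Tmc1 by 2.03 ± 0.24 (3.08e-06) and the tryptophan-degrading enzyme gene Ido2 by 1.67 ± 0.22 (7.19e-06; 24.3 against 8.02 CPM). Igj (2.24), Enkur (2.2), Myo18b (2.02), the T cell receptor subunit gene Cd3e (2.02), Dcdc2a (1.79) and Rab26 (1.62) completed the named increases. Apart from Ssrp1 (-0.89 ± 0.10), the named decreases were Bpifc (-1.45), Trim56 (-1.24), Inhbb (-1.0), Cth (-0.96), Krcc1 (-0.91 ± 0.11, 3.26e-06), Gabrg3 (-0.89), Sdpr (-0.88), Shc4 (-0.85) and Mvp (-0.85). Of these 20 genes 19 passed in every alternative. Inhbb did not pass with the other-cell scores (0.16) or the replicate block (0.071).

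Among the lists, 12 of 20 identity genes were lower and 1 higher on average (median -0.32, camera adjusted p = 4.11e-07, and adjusted p = 0.203 with an estimated correlation), with Ebf1 at -0.55 ± 0.06 and Stmn2 at -0.49 ± 0.08. Of 34 integrated stress response genes 15 were lower and 1 higher (20 and 1 adjusted over the list alone; median -0.29, 4.11e-07, and adjusted p = 0.338 with an estimated correlation), with Ddit3 at -0.61 ± 0.11 and the cystine transporter gene Slc7a11 at -0.60 ± 0.11. Of 25 regeneration-associated genes 10 were lower and 1 higher (median -0.29, 0.000113, and adjusted p = 0.301 with an estimated correlation), with the adhesion gene L1cam at -0.44 ± 0.06. Of the channel genes 10 were lower and 2 higher (median -0.17, 6.23e-05, and adjusted p = 0.338 with an estimated correlation), and of the interferon-stimulated genes 18 were lower (median -1.14, 4.12e-07, and adjusted p = 0.405 with an estimated correlation). Of 18 dissociation and immediate early genes 13 were higher (median 0.63, 1.1e-10, and adjusted p = 0.153 with an estimated correlation), with Hspa1a at 0.94 ± 0.11. Of 77 ribosomal protein genes 19 were higher (median 0.22, 1.72e-06, and adjusted p = 0.338 with an estimated correlation), with Rps12 at 0.83 ± 0.11. Of 19 histone genes 6 were higher (median 0.13, 0.0131, and adjusted p = 0.301 with an estimated correlation), with Hist2h2be at 0.92 ± 0.13. No list passed in this comparison with an estimated correlation. The FACT list (3 lower, 0.151), p53 targets (3 higher, 1 lower, 0.848), DNA repair (1 higher, 2 lower, 0.944), apoptosis (none, 0.529) and DLK-JNK genes (3 higher, 4 lower, 0.311) did not pass as groups.

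Several lists of markers of other cells were higher on average in SSRP1KO with the preset correlation only. Vascular markers were higher in 5 of 12 genes (median 1.61, camera adjusted p = 0.00632), with the pericyte gene Rgs5 at 1.82 ± 0.25, amacrine markers in 6 of 13 (median 0.47, 0.00218), and bipolar markers in 5 of 12 (median 0.48, 0.0262). None of these kept the call in the stricter test (adjusted p = 0.338, adjusted p = 0.338 and adjusted p = 0.453 with an estimated correlation). Microglia and macrophage markers were higher in 3 of 19 (median 0.29, 0.0131, and adjusted p = 0.545 with an estimated correlation) and T cell and neutrophil markers in 1 of 9 (median 1.11, 0.00347, and adjusted p = 0.338 with an estimated correlation). Rod (1 of 16 higher, 0.101), cone (none of 9, 0.151), horizontal cell (2 of 4, 0.16), macroglia (4 of 16, 0.0836) and pigment epithelium markers (1 of 4, 0.411) did not pass.

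The difference between the crush responses of SSRP1KO and NT was tested directly, and it passed in 121 of 16621 genes. In 8 of the 10 genes with the smallest adjusted p, the difference was above 0: the receptor subunit genes Cacng5 (difference of 1.16 ± 0.15 on the log2 scale, averaged over days; adjusted p of the F-test in edgeR = 8.66e-05), Chrna6 (1.64 ± 0.27, 0.00113) and Chrnb3 (1.09 ± 0.18, 0.00283), Mme (2.01 ± 0.48, 0.00226), the chloride transporter gene Slc12a5 (0.86 ± 0.16, 0.00283), Ppp1r17 (1.55, 0.00235), Rassf4 (1.05, 0.00283) and the protocadherin gene Pcdh10 (0.68 ± 0.11, 0.00301). It was below 0 for Atf3 (-2.50 ± 0.31, 0.000675) and the integrin gene Itga5 (-3.06 ± 0.45, 0.00321). For 7 of these 10 genes the larger part of the difference lay before crush. Without crush the log2 difference between SSRP1KO and NT was 2.05 for Atf3 (13.5 and 3.25 CPM), 2.63 for Itga5 (7.80 and 1.26 CPM), -1.0 for Chrnb3 (619 and 1235 CPM) and -0.86 for Cacng5 (161 and 293 CPM). It was -0.51 for Pcdh10, -0.81 for Ppp1r17, -0.77 for Chrna6, -0.47 for Slc12a5, -0.16 for Mme and 0.03 for Rassf4. The uncrushed groups differed in sex and included the library labelled SSRP1KO no crush replicate 3. The count was 626 with DESeq2, 1111 without the 3 libraries that stood apart and 537 without the libraries at 2dpc. It was 262 without the library labelled NT 2dpc replicate 3, 325 without SSRP1KO 2dpc replicate 5, 60 without NT no crush replicate 2, 78 without SSRP1KO 3dpc replicate 3, and 71 and 61 without SSRP1KO 4dpc replicates 2 and 3.

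LINE elements are retrotransposons, and the share of counts on intervals annotated as LINE did not pass a test between SSRP1KO and NT. The repeat table held 205758 intervals, of which 92.5% were 26 bases long, and 18220 were annotated as LINE, 17695 of them L1. LINE counts made up 1.98% of the table, ribosomal RNA repeats 60.3% and intervals without a family 30.4%. The LINE share of gene counts was 1.06 ± 0.140% in NT no crush and 0.857 ± 0.280% in SSRP1KO no crush, 1.06 ± 0.0775 and 1.05 ± 0.0852% at 1dpc, 0.809 ± 0.205 and 0.918 ± 0.199% at 2dpc, 0.964 ± 0.154 and 1.00 ± 0.0881% at 3dpc, and 0.906 ± 0.0771 and 1.02 ± 0.182% at 4dpc (n = 3 each). The mean log2 difference was 0.01 (two-sided permutation test within times, p = 0.908, 15 libraries against 15). In NT, crushed and uncrushed libraries differed by -0.19 (exact test, p = 0.275, 12 against 3). A single interval on chromosome 13 from 9834403 to 9834449 held 40.2% of all LINE counts, and 2 intervals beside it held 16.7% and 8.19%. Without the 10 highest intervals the difference between SSRP1KO and NT was 0.13 (permutation test within times, p = 0.0905). Without crush the share then stood at 0.280 ± 0.0198% in SSRP1KO and 0.212 ± 0.0105% in NT, the opposite direction to the share of all LINE counts. The 3 libraries of each group, with 0.294% in the library labelled SSRP1KO no crush replicate 3, did not overlap, which chance gives in 10% of such comparisons, and this time was not tested alone. Without the 10 highest intervals the difference between crushed and uncrushed NT was 0.067.

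Of 1661 LINE intervals tested, 45 passed, 26 higher and 19 lower in SSRP1KO. An L1 interval between genes on chromosome 2, from 94524415 to 94524489, had no count in any NT library and stood at 0.944 ± 1.90 CPM in SSRP1KO (n = 15), and another on chromosome 1, from 132846547 to 132846572, had none in NT and stood at 0.377 ± 0.736 CPM. The next was on chromosome 6, from 89267254 to 89267279 (0.0141 against 0.268 CPM). The 3 named decreases lay in exons, on chromosome 2 from 169633419 to 169633458 in Tshz2 (-0.88 ± 0.16) and at 2 places on chromosome 13 in Map1b, a microtubule-associated protein gene (from 99433993 to 99434092, -0.73 ± 0.14, and from 99434141 to 99434226, -0.67 ± 0.13). Of the 45 intervals 19 lay in exons, 11 in introns and 15 between genes. The count was 71 with no filter and 17 with the replicate block.

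**Figure D5:**
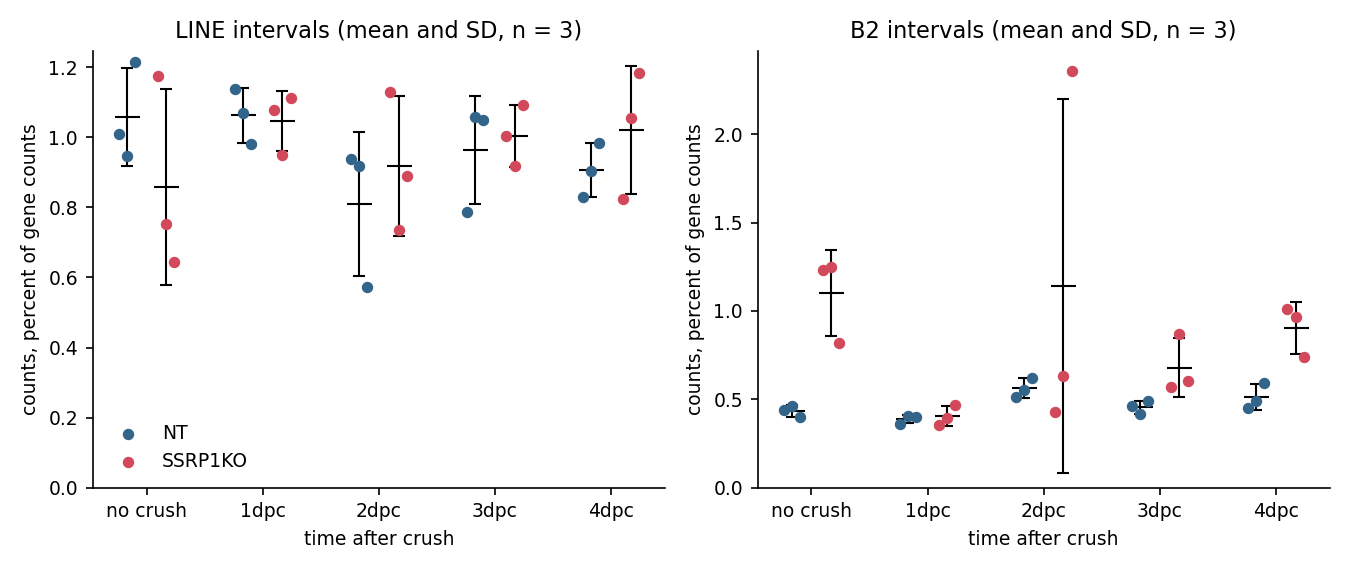
Counts on intervals annotated as LINE and as B2, as percents of the gene counts of the same library (y axes, from 0), against the time after crush (x axes); points are libraries and bars the mean and SD of 3. The LINE points of NT and SSRP1KO overlap at each time, and the B2 mean without crush is 0.434% in NT and 1.10% in SSRP1KO.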

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

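In this part, the tests of unspliced RNA and of the 3 libraries apart for B2, of a smaller response of all injury genes, and of exonic and genomic length were chosen only after the result was seen. The sex and other-cell scores were also chosen after seeing the data, and B2 itself was looked at only then.

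The crush response differed between SSRP1KO and NT in 121 genes, by a test of the difference itself. On the log2 scale, averaged over days, the difference was 1.16 for Cacng5, -2.50 for Atf3, 1.64 for Chrna6, 2.01 for Mme, 1.55 for Ppp1r17, 1.05 for Rassf4, 1.09 for Chrnb3, 0.86 for Slc12a5, 0.68 for Pcdh10 and -3.06 for Itga5. Of 80 shuffles of the sgRNA labels within time, 3 gave as many genes, the real one included, a share under 0.05, but the highest other shuffle gave 300.

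As groups, the median difference between the crush responses was -0.60 for the integrated stress response (camera adjusted p = 4.72e-12, and adjusted p = 0.18 with an estimated correlation), -0.34 for regeneration-associated genes, -0.060 for p53 targets and -0.12 for apoptosis genes. It was 0.35 for cholesterol biosynthesis, 0.39 for voltage-gated channels, 0.26 for synaptic vesicle genes, 0.40 for ganglion cell identity and 0.45 for subtype markers. Amacrine (-0.61), microglia and macrophage (-1.76), and T cell and neutrophil markers (-1.21) also differed, as did ribosomal proteins (-0.23) and oxidative phosphorylation (0.12). With an estimated correlation no list had an adjusted p under 0.118. The uncrushed groups enter each of these differences, and they include the library labelled SSRP1KO no crush replicate 3 and differ in sex.

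A pattern weighed was the smaller crush response in SSRP1KO at 4dpc, where the 2 injury lists (integrated stress response and regeneration-associated genes) had a median log2 difference of -0.60 from NT. Dilution by the other cell types scored was argued against by a median of -0.59 with the other-cell scores as covariates (quartiles -0.88 to -0.32). The sex of the animals was argued against by a median of -0.63 with the sex score (quartiles -0.95 to -0.37). The other-cell scores of NT and SSRP1KO overlapped at 4dpc, so these covariates could move the median little. The scores hold no list of ganglion cell genes, so dilution by uninjured ganglion cells was not tested. Of 1183 genes down at least 2-fold in NT at 3dpc, 223 were higher and 8 lower in SSRP1KO at 4dpc, and of 1019 genes up at least 2-fold, 142 were lower and 8 higher. A smaller response of all injury genes may therefore be the pattern, as a hypothesis. These counts were not computed without NT 4dpc replicate 1, without which 553 genes differed at 4dpc, against 1149. The libraries of the groups differed in other ways at 4dpc. Rn45s held 10.4, 12.2 and 13.8% of counts in SSRP1KO and 5.42, 6.09 and 6.35% in NT. Genes detected were 17927 to 18504 in SSRP1KO and 15899 to 17012 in NT. Whether RNA or library quality bears on the pattern was not tested. Whether fewer cells were injured or surviving cells responded less through loss of Ssrp1 stays open, since no count of injured cells is held here.

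Another pattern was in repeat intervals outside the LINE comparison. The B2 share of gene counts, from short retrotransposons transcribed by RNA polymerase III, was higher in SSRP1KO by 0.67 on the log2 scale (permutation test within times, p = 0.00023; adjusted over 32 family tests, 0.00331), and by 1.32, 0.05, 0.62, 0.56 and 0.81 at the 5 times. The value at 2dpc rested on SSRP1KO 2dpc replicate 5 (2.36%), since the other 2 SSRP1KO libraries stood at 0.431 and 0.632% and the NT ones at 0.513 to 0.623%. Of 10473 B2 intervals 3005 were higher and 59 lower, against 23 and 16 of 5675 Alu intervals. In an intron of Jpt1, on chromosome 11 from 115509314 to 115509346, B2 counts stood at 0.543 ± 0.315 CPM in NT and 9.40 ± 9.12 CPM in SSRP1KO (n = 15 each), and at 1.02 CPM in the library labelled SSRP1KO no crush replicate 3.

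More unspliced RNA or genomic DNA would raise B2 and Alu in introns alike, and the difference between them was 0.78 (permutation p = 1e-05, the smallest these permutations can give). This argues against it as the whole cause, but it may be part of the difference without crush. There intronic B2 was higher by 1.66, and intronic Alu by 1.06, ERV1 by 0.43, L1 by 0.64, ERVK by 0.75, ERVL-MaLR by 0.84 and B4 by 0.88. Without the 10 highest intervals the B2 difference was 0.71 (permutation p = 0.00033), and without the 3 libraries that stood apart it was 0.58 (permutation p = 0.00057), which argues against a few intervals and against those libraries as the whole cause. An effect of the loss of Ssrp1 on B2 may remain, as a hypothesis. The size of the difference in the whole B2 share did not follow that of the Ssrp1 mRNA. At 1dpc, where Ssrp1 differed by -1.34, B2 differed by 0.05. Without crush, where the Ssrp1 difference did not pass, B2 differed by 1.32. In introns at 1dpc, B2 differed by 0.09 and Alu by -0.50, so B2 was higher relative to Alu at 1dpc too. Whether the gap between B2 and Alu followed the Ssrp1 mRNA was not tested. Sex, the day of preparation and how the intervals were chosen stay open, as they were not tested.

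The last pattern was gene length: longer genes were lower in SSRP1KO on average, with a rank correlation of -0.189 over 15775 genes and medians from 0.12 (under 10 kb) to -0.15 (over 200 kb). Of 80 shuffles 3 reached that size, the real one included, and the highest other was 0.217. With the other-cell scores as covariates the correlation was -0.225, which argues against the other cell types scored. Exonic length given genomic length gave -0.116, a size reached by 1 of 80 shuffles, the real one (highest other 0.0978), so exonic length may carry the pattern, as RNA quality or library chemistry could. For genomic length given exonic length the value was -0.0682, reached by 11 of 80 shuffles (highest other 0.107), so an effect of genomic length cannot be told apart from chance.

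For the average of SSRP1KO against NT, 1 of 80 shuffles gave 3296 genes, the real one (highest other 517), and for LINE intervals 1 of 80 gave 45 (highest other 5). Chance was therefore unlikely for both but not excluded, since 1 of 80 is the smallest share possible here. The labels also do not say that the libraries came from separate animals. For lists in the average, 6 of 80 gave as many as the 16 called (highest other 17), so chance was not excluded. The median of the other shuffles was 7 lists called, so camera with the preset correlation called lists under shuffled labels too. In the comparisons of 3 libraries with 3, 10 splits cannot give a share under 0.05. The real counts and the highest of the other splits were 309 and 0, 3128 and 93, 4015 and 0, and 4513 and 1 for NT at 1dpc to 4dpc, with 1 split as large in each. They were 672 and 0, 1939 and 1044, 2414 and 12, and 2174 and 0 for SSRP1KO, again with 1 split. For SSRP1KO against NT they were 650 and 34 without crush, 3 and 0 at 1dpc, 14 and 20 at 2dpc (2 splits as large), 184 and 0 at 3dpc, and 1149 and 0 at 4dpc.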

How the results depend on the processing

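In this part, the tests with the sex score, the other-cell scores, the 3 libraries apart left out and Rn45s left out were chosen only after the result was seen; the cause of a moved count was not tested.

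With DESeq2 the counts were 575 (NT 1dpc), 1084 (SSRP1KO 1dpc; 655 up, 429 down, against 504 and 168), 1222 (SSRP1KO against NT without crush; 650 higher, 572 lower, against 239 and 411), 29 (1dpc), 639 (2dpc; 429 and 210, against 12 and 2), 568 (3dpc) and 626 (difference between responses). With only the libraries compared they were 880 (NT 1dpc; 404 up, 476 down, against 230 and 79), 1870 (NT 2dpc), 268, 192 and 1157 (SSRP1KO at 1dpc, 2dpc and 3dpc), and 14, 345, 0 and 705 (SSRP1KO against NT without crush and at 1dpc, 2dpc and 3dpc; 298 higher and 407 lower at 3dpc, against 125 and 59). No filter gave 8 (1dpc), 26 (2dpc) and 71 LINE intervals.

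Replicate numbers did not pair the libraries (median correlation -0.00418 over 117 pairs with the same number). With the replicate block the counts were 693 (SSRP1KO 2dpc), 978 (SSRP1KO against NT without crush), 0 (2dpc), 290 (3dpc) and 17 LINE intervals. Of the SSRP1KO 2dpc libraries 2 have a number of their own, so the block leaves 1 library to carry the comparisons of that group, and its 693 and 0 say nothing about stability.

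With the sex score they were 159 (NT 1dpc), 2909 (NT 4dpc), 154 and 885 (SSRP1KO 1dpc and 2dpc), and 19 and 0 (SSRP1KO against NT without crush and at 2dpc). With the other-cell scores they were 993, 10 and 0 (SSRP1KO against NT without crush, 1dpc and 2dpc). Without the 3 libraries apart they were 998 (NT 1dpc), 1772 (SSRP1KO 1dpc), 2416, 50, 5, 1071 and 2460 (SSRP1KO against NT without crush to 4dpc), and 1111 (difference between responses), which was 537 without the libraries at 2dpc. None of the 3 libraries apart was in NT no crush or in the groups of 1dpc, 3dpc and 4dpc. In edgeR the 0 counts at 2dpc stand beside 2961 genes with an unadjusted p under 0.05 in the fit of all libraries.

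The LINE share of crushed against uncrushed NT was 0.067 without the 10 highest intervals, against -0.19, and that of SSRP1KO against NT was -0.11 on the TMM-scaled library size, against 0.01. With an estimated correlation 54 of 187 list calls passed, and with fry 135 passed in the same direction.

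With each library left out in turn, counts ran from 162 to 297, 2252 to 3005, 3173 to 3454 and 3767 to 4154 (NT 1dpc to 4dpc), from 277 to 742, 1636 to 2015, 1756 to 2288 and 1501 to 2073 (SSRP1KO), from 160 to 1192, 0 to 2, 0 to 736, 19 to 116 and 464 to 1014 (SSRP1KO against NT without crush to 4dpc), from 2795 to 3699 (average), from 60 to 325 (difference between responses) and from 37 to 60 (LINE intervals). Ssrp1 ran from -0.95 to -0.84, the LINE share from -0.039 to 0.047, and in NT from -0.26 to -0.08. Of 6792 values of named genes with a library left out, 908 no longer passed and none changed direction. These genes were chosen because they passed with all libraries, many with no overlap between the groups. A change of direction was therefore hardly possible.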

Other observations

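No test in this part was chosen before the result was seen. Several genes that changed after crush in NT cells had other levels in SSRP1KO cells before any crush. Itga5, an integrin that binds fibronectin, stood at 1.26 CPM in uncrushed NT and reached 64.5 ± 10.3 CPM at 4dpc, and in SSRP1KO it went from 7.80 ± 5.20 to 30.1 ± 2.67 CPM (n = 3 each). Chrna6 went from 528 ± 31.8 to 13.3 ± 4.23 CPM in NT and from 309 ± 70.9 to 54.6 ± 11.5 CPM in SSRP1KO, and Chrnb3 from 1235 ± 13.3 to 139 ± 13.4 CPM and from 619 ± 90.9 to 220 ± 19.4 CPM. The uncrushed Itga5 level includes 13.4 CPM in the library labelled SSRP1KO no crush replicate 3, against 6.94 and 3.08 CPM in replicates 1 and 2.

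The library labelled SSRP1KO no crush replicate 3 had Ssrp1 at 66.9 CPM. With that library left out, 12 genes and 13 B2 intervals separated the other 14 SSRP1KO libraries from the 15 NT libraries, and it lay in the NT range for 8 of the genes and 8 of the intervals. These 8 and 8 are those that this library alone kept from separating the groups. Its place in the NT range for them follows from that choice and does not test its label. Among the other libraries, none lay in the other range for more than 2 genes, and for B2 intervals SSRP1KO 1dpc replicate 1 did so for 7 of 12. The library labelled NT 2dpc replicate 3 had Ssrp1 at 36.1 CPM and the lowest total, and lay in the other range for none of 4 genes and 3 of 8 intervals. The 4 genes separated the groups with this library included, so its counts do not test its label either. Both libraries were used as labelled.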
